A study of Mus musculus with 15 samples.

How the data were processed

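Ribosome footprints and 3′ mRNA were measured in 15 libraries of mouse dorsal root ganglion cultures, 8 by ribosome profiling and 7 by QuantSeq, in the groups described in the results. Per the submitters' processing notes, FastQC 0.11.5, TopHat2 2.1.1, Cufflinks 2.2.1 and the genome build mm10 were used; the notes give no order or role for the tools, and the rule for counting reads and the annotation release are not stated. Most of the genes listed are protein-coding: 21555 of 21958 have a coding length in GENCODE vM21.

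The deposited table holds 21958 genes with a value for each library in each of 2 scalings. Per the file headers, one set of columns is TPM normalised against all protein-coding genes. In each library these values add up to 1e+06 within rounding. Of the non-zero values, 94.7% to 97.7% are whole multiples, within 0.01 read, of 1 step that is the same for every gene. The authors' values thus carry no gene length term and are used here as CPM (reads per 1e+06 reads of the genes listed). The other deposited set, called scaled and 90th percentile normalised per the file headers, is the ratio of the same values to 1 constant per library. Depth per library was taken as 1e+06 divided by the step, and a level of 3 reads was taken as the smallest dependable signal. Fractions of a step occur at some genes, so counts of whole reads were not used for the tests. Samples were grouped by the strain, assay and treatment in the labels. The labels do not say whether libraries of 1 group came from separate animals or cultures, so p-values measure the spread between these libraries only. Libraries of different assays or groups share a replicate number without a stated pairing, and the numbers were used as a block only in an alternative. Treated cultures are numbered below by their libraries, which does not mean that both assays read the same culture.

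All tests used R 4.3.3 and limma 3.58.1. Values were log2 of CPM plus 1. Genes with a mean of at least 5 CPM over the libraries compared were kept (in each assay where both were used), group means were fitted with moderated variances and an abundance trend, and two-sided p-values were adjusted by Benjamini and Hochberg's method over the genes tested, with a threshold of 0.05. Treatment was taken within Swiss Webster, and the C57BL/6 footprint libraries added to the estimate of the spread. The single C57BL/6 QuantSeq library, alone in its group, added nothing to it. The ratio of footprints to mRNA was tested with an interaction term in 1 model over all 15 libraries. Errors of log2 values are standard errors from limma, and errors of CPM are standard deviations.

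Before the data were examined, 31 lists with 866 entries were fixed from general knowledge (cell-type markers, signalling pathways, protein complexes), of which 861 entries are in the table. Some genes, such as Ngfr and Csf1, stand in several lists, so the lists are not independent of each other. The 30 lists with at least 3 measured members were tested with camera in limma, two-sided, at its preset correlation of 0.01, adjusted over the lists of 1 comparison. With an estimated correlation, 0 of the lists called by camera held in any of the 5 comparisons. A second test, fry, which asks whether the genes of a list move on balance one way, called 3 lists for footprints by treatment, 0 for QuantSeq by treatment, 0 for the ratio by treatment, 4 for strain and 19 for footprints against QuantSeq. Counts of members are given over all genes and adjusted over the list alone.

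The rule for named genes was also fixed before the data were examined. Per comparison it took, among called genes whose libraries did not overlap, the 10 with the largest rise and the 10 with the largest fall, leaving out unnamed gene models. Where fewer than 5 passed in a direction it was filled to 5 by the lowest p. It added up to 4 members of each list by lowest p, and Fos, Egr1, Junb, Arc, Ntrk1, Il6ra, Calca, Scn10a and Mpz where measured. The list members named in the text are a part of those, chosen after their values were seen, as were the genes whose positions are printed. Coordinates and coding lengths came from GENCODE vM21 on the same build; 21790 genes matched and 168 did not, and 21555 had a coding length. In the table, 37 symbols stand for 79 entries, and 4913 genes share a locus entry with another gene.

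Each model was tested on simulated data with genes changed by known amounts, using the means, depths and spread of the real libraries. Every library was drawn independently, so the false calls do not cover structure within a group, such as a gap between treated libraries. Of genes changed 2-fold, 46.2% were recovered for footprints by treatment (4 false among 99 calls), 34.9% for QuantSeq by treatment (0 of 76), 20.9% for the ratio by treatment (2 of 72), 29.9% for strain (2 of 78) and 93.8% for footprints against QuantSeq (8 of 161). Of genes changed 1.5-fold, 13.4%, 3.08%, 1.49%, 1.54% and 53.7% were recovered in the same order, so changes of that size were mostly missed in the first 4 comparisons.

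Alternatives fixed before the data were examined were an added value of 0.1 or 5 CPM, a mean of at least 1 or 20 CPM or no filter, quantile normalisation, TMM factors, robust variances, pooled naive groups, Swiss Webster libraries alone, the replicate number as a block, weights per assay, and leaving out each library in turn. Those added after the data were seen were the authors' percentile scaling, voom weights, treated cultures 1 and 2 or 3 and 4 alone, and 2 treatments of coding length: a smoothed trend removed from each library, and footprints per kilobase. Outlying libraries among the 4 treated ones were sought with Dixon's ratio over the genes named in the text, 30 lists per assay and the depths, 147 groups in all. Files were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No sequence reads were analysed here.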

Results

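Ribosome footprints and 3′ mRNA ends were sequenced from dorsal root ganglion cultures, which hold the cell bodies of sensory neurons together with glia and other cells. The ganglia came from 4-week-old mice, and the cultures were kept for 6 days. Treated cultures received nerve growth factor (NGF, a growth factor that sensitises pain-sensing neurons) at 20 ng/mL together with interleukin-6 (IL-6, an inflammatory cytokine) at 50 ng/mL for 20 min. Emetine, which arrests ribosomes on mRNA, followed for 1 min. Of the 15 libraries, 8 were ribosome profiling libraries of 28 to 34 nt footprints and 7 were QuantSeq libraries of total RNA, which read the 3′ end of polyadenylated mRNA. The footprint libraries comprised 2 of naive C57BL/6 cultures, 2 of naive Swiss Webster cultures and 4 of treated Swiss Webster cultures. The QuantSeq libraries comprised 1, 2 and 4 of the same groups. No treated C57BL/6 culture was used here.

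Depth, from the smallest step between values, was 1.49 to 3.31 M reads (M, 1e+06) in the footprint libraries and 9.96 to 19.5 M reads in the QuantSeq libraries. A gene with 3 reads had 0.906 to 2.01 CPM (reads scaled to the same total over the genes listed in every library) in footprints and 0.154 to 0.301 CPM in QuantSeq. These limits cover counting error only. Ribosomal protein genes were here picked by symbol (Rpl, Rps or Rplp and a digit, or Rpsa). That choice can take in other genes and differs from the list tested below. Genes picked so took 1.88% ± 0.0448 (SD, n = 2) of footprint reads in Swiss Webster naive cultures, 2.03% ± 0.0120 (n = 2) in C57BL/6 naive cultures and 2.47% ± 0.179 (n = 4) in treated cultures. In QuantSeq they took 7.39% ± 0.0521 (n = 2) in Swiss Webster naive cultures and 9.68% ± 1.82 (n = 4) in treated cultures, and 10.5% in the single C57BL/6 library. The treated libraries numbered 1 and 2 stood apart from those numbered 3 and 4 in neuronal genes in both assays. The means of 4 lists of neuronal genes were lower in the first pair by a median log2 difference of -0.79 in footprints and -0.84 in QuantSeq. Across all footprint genes kept, libraries 3 and 4 correlated at 0.965, above their values with 1 and 2 (0.933 to 0.956). In QuantSeq 3 and 4 were not such a pair. They correlated at 0.964, about as with library 1 (0.963 and 0.964), against 0.984 between 1 and 2.

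The first comparison asked which footprints differed between treated and naive Swiss Webster cultures, the level of ongoing protein synthesis 20 min after the treatment. Rapid-response genes were among the few footprints that rose. Btg2, an antiproliferative immediate early gene, rose from 80.1 ± 16.9 CPM (SD, n = 2) in naive cultures to 219 ± 64.9 CPM (n = 4), and Zfp36, whose product binds AU-rich elements and speeds the decay of inflammatory mRNAs, rose from 78.0 ± 29.7 to 193 ± 43.6 CPM. Footprints of 5 of 82 ribosomal protein genes rose: Rps21 went from 223 ± 6.22 to 488 ± 42.9 CPM and Rpl36a from 74.6 ± 1.52 to 174 ± 17.1 CPM. Of 17 Schwann cell markers, 4 fell, among them Sox10, the transcription factor of the Schwann lineage, from 342 ± 9.43 to 179 ± 15.2 CPM. The largest fall was that of Wtap, a subunit of the complex that methylates adenosine in mRNA, from 822 ± 71.6 to 77.4 ± 26.5 CPM.

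By the limma test, 14 of 11144 genes rose and 42 fell at an adjusted p below 0.05; at an unadjusted p below 0.05 there were 1025 higher and 753 lower, the opposite balance. In 25.7% of all genes the 4 treated and 2 naive libraries did not overlap, where chance gives 13.3%. Among the genes that rose were Wisp2 (log2 fold change 1.42, SE 0.25, adjusted p = 0.042), a secreted protein of fibroblasts and other mesenchymal cells, Btg2 (1.40, SE 0.26, adjusted p = 0.048), Zfp36 (1.32, SE 0.25, adjusted p = 0.049), the endothelin receptor Ednra (1.11) and Medag (1.11). Mfap5, a microfibril protein of fibroblasts, also rose (0.80, adjusted p = 0.041). The larger falls were those of Wtap (-3.45, SE 0.25, adjusted p = 2.8e-04), Foxe1 (-3.34), Tspan33 (-3.30), Chrdl2 (-2.33), Tlx3 (-1.88), a transcription factor of sensory and other neurons, Dact3 (-1.81) and Mrpl14 (-1.72). Plxnb3 (-1.61), the transferrin gene Trf (-1.57) and Eml6 (-1.50) fell less. Foxe1 and Chrdl2 in treated cultures, at 1.01 ± 0.737 and 2.19 ± 0.826 CPM, lay near the level of 3 reads, so their folds depend on the 1 CPM added before the log. In QuantSeq, Foxe1, Tspan33 and Chrdl2 stood at 1.03 CPM or less in every library, so their mRNA was not tested. Of the 14 genes that rose, 7 had a C57BL/6 naive mean nearer to the treated than to the Swiss Webster naive mean. In Medag (164 and 174 CPM), Rpl37a (209 and 178 CPM) and Rpl30 (220 and 201 CPM) the C57BL/6 footprints lay within the treated range. Of the 42 genes that fell, 16 had a C57BL/6 naive mean nearer to the treated mean. Within or below the treated range lay C57BL/6 footprints of Foxe1 (1.48 and 0.83 CPM), Tlx3 (17.7 and 18.3 CPM) and Mrpl14 (21.8 and 24.9 CPM). On mm10, Wtap lies on chromosome 17 from 12966796 to 12994169, Btg2 on chromosome 1 from 134075170 to 134079120, Rps21 on chromosome 2 from 180257377 to 180258445 and Sox10 on chromosome 15 from 79154908 to 79165240.

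Immediate early genes as a list rose in footprints. Of 30 measured members, 2 rose among all genes, and adjusted over the list alone 9 rose and 1 fell (median log2 0.30, camera adjusted p = 0.0036, adjusted p = 0.59 with an estimated correlation). Members that did not pass among all genes had large values: Ier2 1.56 (SE 0.36, adjusted p = 0.089), Egr1 1.13 (SE 0.27, adjusted p = 0.096) and Fos 1.46 (SE 0.36, adjusted p = 0.10). Junb had 0.32 (adjusted p = 0.23), and Arc, a synaptic immediate early gene, had 1.58 ± 0.591 CPM in naive and 9.74 ± 4.94 CPM in treated cultures (adjusted p = 0.14). Footprints of Fos were 175 ± 114 CPM in naive and 448 ± 130 CPM in treated cultures, and those of Egr1 were 489 ± 292 and 974 ± 62.6 CPM. The list was no longer past the threshold without treated footprint library 2 (median 0.23, adjusted p = 0.13), nor with treated cultures 3 and 4 alone (median 0.15, adjusted p = 0.44).

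**Figure D1:**
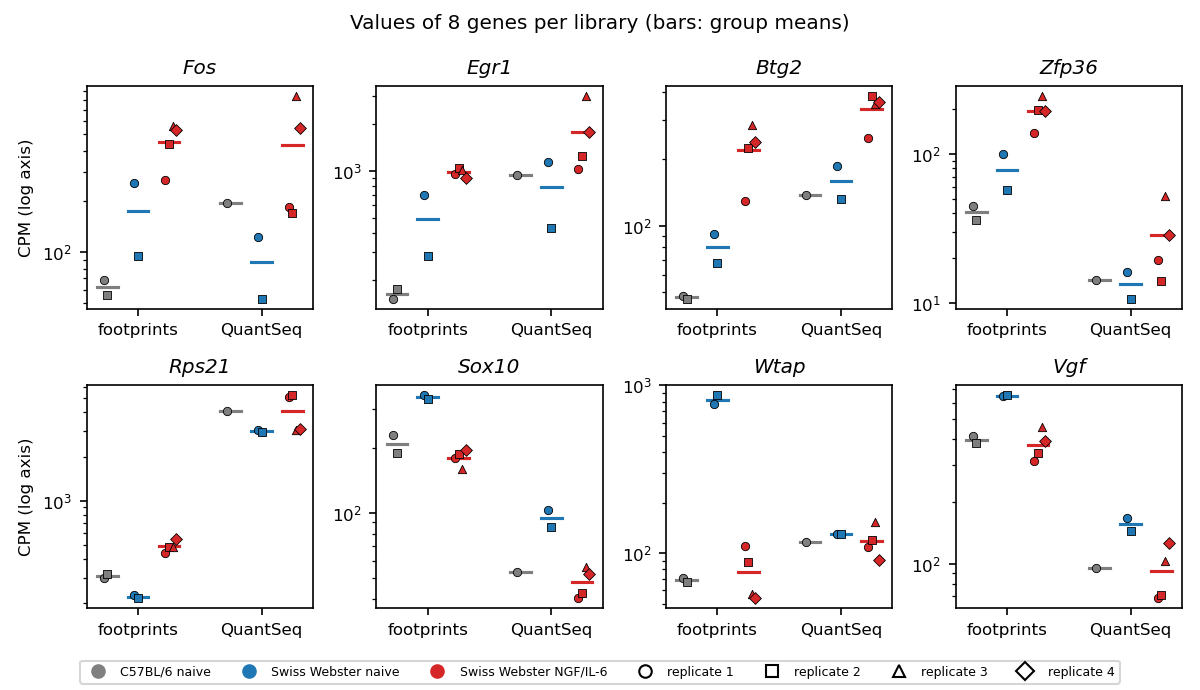
Values of 8 genes per library in CPM on a log axis, for ribosome footprints (left in each panel) and QuantSeq mRNA (right). Colours give the group, marker shapes the replicate number and bars the group mean; Wtap footprints stood at 771 and 873 CPM in the Swiss Webster naive libraries and at 54.2 to 110 CPM in the treated ones.

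Ribosomal protein genes had the lowest camera p of the 30 lists in this comparison. Of 82 measured members, 73 had a value above 0, 5 rose among all genes and 31 rose adjusted over the list alone. Besides Rpl36a (1.20, SE 0.13, adjusted p = 0.006) and Rps21 (1.13, SE 0.12, adjusted p = 0.0046), these were Rpl37a (0.99), Rpl30 (0.95) and Rpl28 (0.93). The list median was 0.48 (camera adjusted p = 1.9e-18, adjusted p = 0.13 with an estimated correlation). Their coding sequences are short, with a list median of 453 bases, and across all genes with a known length the footprint fold change fell with coding length (Spearman's rho -0.31). The QuantSeq fold change by treatment fell with coding length too (rho -0.26). Once a trend on coding length was removed, the ribosomal protein median was 0.25 (camera adjusted p = 2.9e-08, adjusted p = 0.69 with an estimated correlation). The 74 nuclear subunits of the respiratory chain, also short, rose as a list (median 0.22, camera adjusted p = 1.4e-04, adjusted p = 0.59 with an estimated correlation) with 0 members past the limma threshold. That list call ended once a trend on coding length was removed (median 0.05, adjusted p = 0.41). The 23 measured genes of the integrated stress response rose as a list (median 0.27, camera adjusted p = 0.027, adjusted p = 0.59 with an estimated correlation), 3 of them adjusted over the list alone. Their values were 0.75 for Cebpb, 0.54 for the serine synthesis enzyme Psat1 and 0.42 for Atf5. This call was lost without treated library 1 (camera adjusted p = 0.059) or 2 (0.088) and with treated cultures 3 and 4 alone (median 0.23, adjusted p = 0.22). It was lost too without Swiss Webster naive library 1 (median 0.28).

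Schwann cell markers fell as a list, with 4 of 17 measured members lower among all genes and 7 adjusted over the list alone (median -0.53, camera adjusted p = 2.7e-07, adjusted p = 0.13 with an estimated correlation). The 4 were Sox10 (-0.93, SE 0.13, adjusted p = 0.015), the adhesion molecule L1cam (-0.997), the neuregulin receptor Erbb3 (-1.04) and the GDNF receptor Gfra1 (-0.79), and neurons also express L1cam and Gfra1. The myelin gene Mpz had 0.06 (adjusted p = 0.92). Satellite glia markers fell as a list too (14 members, median -0.25, camera adjusted p = 0.014, adjusted p = 0.30 with an estimated correlation), and adjusted over the list alone 4 fell and 1 rose. Cdh19 had -1.02, Ttyh1 -0.80 and the potassium channel Kcnj10 -0.76. The satellite glia call was lost without Swiss Webster naive library 2 (median -0.09) and with treated cultures 3 and 4 alone (-0.11, camera adjusted p = 0.083). Macrophage markers fell as a list (20 members, median -0.30, camera adjusted p = 0.033, adjusted p = 0.81 with an estimated correlation), but without treated library 3 the median was -0.03 (adjusted p = 0.85), and without Swiss Webster naive library 1 it was -0.22 (adjusted p = 0.13). Trem2 had -0.58 and C1qb -0.59.

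Pan-neuronal genes (27 members, median -0.25, camera adjusted p = 0.0086) and neuropeptide and secretory granule genes (19 members, median -0.11, camera adjusted p = 0.033) were lower as lists, each with adjusted p = 0.81 with an estimated correlation. Both medians were above 0 with treated cultures 3 and 4 alone, at 0.20 and 0.16. Without treated library 1 they were -0.06 (adjusted p = 0.25) and 0.02 (adjusted p = 0.38). Without treated library 2 they were -0.08 (adjusted p = 0.13) and -0.05 (adjusted p = 0.15), and without Swiss Webster naive library 1 the second was no longer past the threshold (adjusted p = 0.10). Atp1a3 had -0.61 and Stmn3 -0.65. Vgf, a neuropeptide precursor induced by nerve growth factor, fell (-0.80, SE 0.15, adjusted p = 0.048), from 647 ± 4.94 to 375 ± 62.6 CPM. Cytoskeleton genes were lower as a list (25 members, median -0.23, camera adjusted p = 0.0028, adjusted p = 0.13 with an estimated correlation), with the motor protein Dync1h1 at -0.70 (adjusted p = 0.069). Calca (0.33) and Scn10a (-0.41) of pain-sensing neurons, the NGF receptor Ntrk1 (-0.17) and the IL-6 receptor Il6ra (-0.42) did not pass, and the 20 nociceptor markers were not past the threshold as a list (median -0.16, camera adjusted p = 0.14).

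The genes called depended on single libraries. Without Swiss Webster naive library 2, Wtap alone was called; the count was 2 without naive library 1, 26 without either C57BL/6 library, 24 without treated library 4 and 155 without treated library 3. Without treated library 2, 6 lists were called in place of 10.

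**Figure D2:**
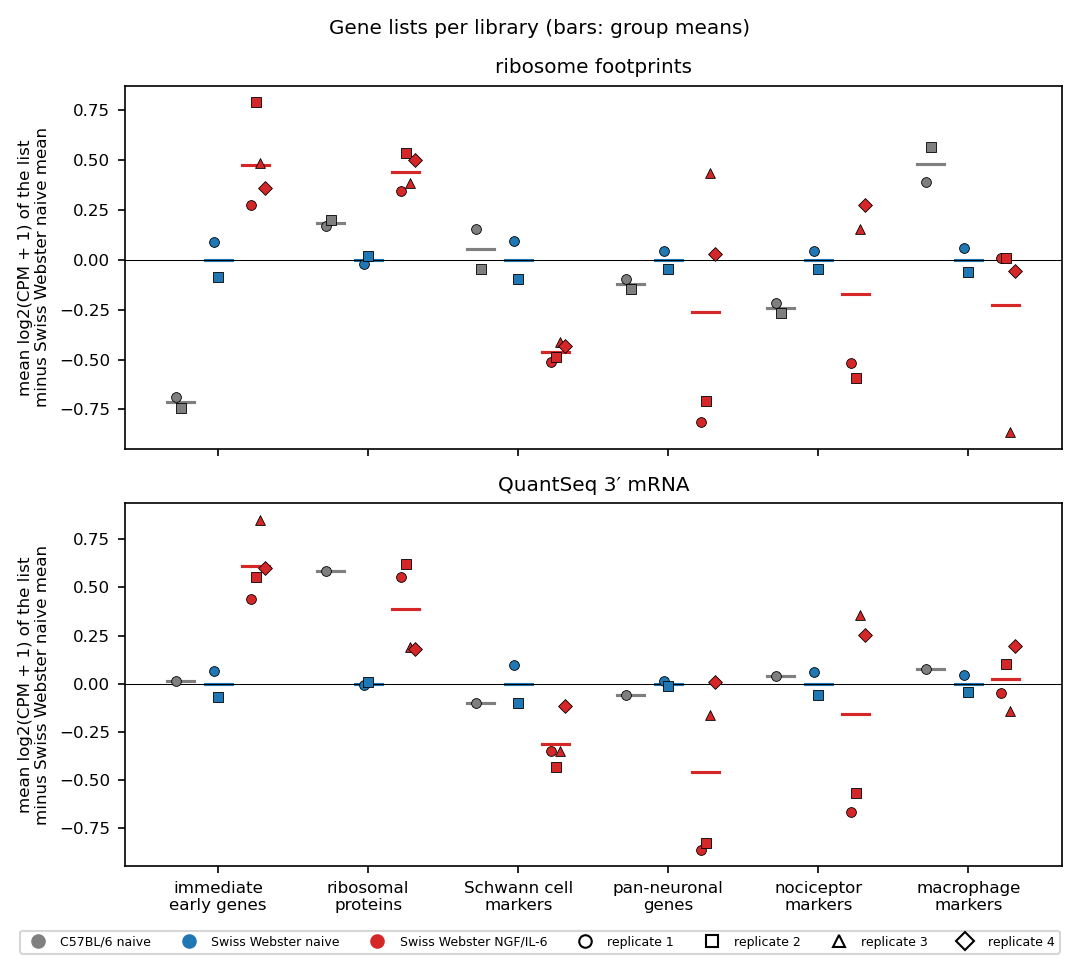
Mean log2(CPM + 1) of the members of 6 lists in each library, minus the Swiss Webster naive mean, for footprints (top) and QuantSeq (bottom); points are libraries and bars are group means. Pan-neuronal genes and nociceptor markers parted treated libraries 1 and 2 from 3 and 4, and ribosomal protein genes were higher in the single C57BL/6 QuantSeq library (0.59) than in the Swiss Webster naive mean.

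The second comparison asked how mRNA level at the 3′ end differed between treated and naive Swiss Webster cultures. As lists, immediate early genes and ribosomal protein genes were higher and pan-neuronal and Schwann cell genes lower, as in footprints, by camera at its preset correlation. The first had adjusted p = 0.24 with an estimated correlation, and the others adjusted p = 0.62. Of single genes, 1 of 9802 rose and 0 fell by limma; at an unadjusted p below 0.05 there were 216 higher and 625 lower. In 20.9% of genes the libraries did not overlap, where chance gives 13.3%. The gene that rose was Pde2a, a cyclic nucleotide phosphodiesterase, listed at less than 1 read per library in Swiss Webster naive cultures and at 18.9 ± 7.79 CPM (SD, n = 4) in treated ones (adjusted p = 0.011); it stood at 14.6 CPM in the naive C57BL/6 library. The table holds this symbol under 2 gene identifiers, so the value is uncertain, and its call was lost without either Swiss Webster naive QuantSeq library or without treated library 1 or 4.

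Of 28 measured immediate early genes, 0 passed in limma over all genes and 10 rose adjusted over the list alone (median 0.50, camera adjusted p = 1.6e-09, adjusted p = 0.24 with an estimated correlation). Nr4a1, an orphan nuclear receptor, had 1.69 (SE 0.20, adjusted p = 0.082), and it passed without treated QuantSeq library 2. Fos had 2.08 (SE 0.64, adjusted p = 0.43), Egr1 1.20 (SE 0.48), Klf2 1.11, Btg2 1.08, Klf4 0.94 and Junb 0.62. Egr1 stood at 1131 and 432 CPM in the Swiss Webster naive libraries. It stood at 1020 and 1234 CPM in treated libraries 1 and 2 and at 2998 and 1780 CPM in 3 and 4. Fos stood at 123 and 53.2 CPM in naive libraries, 185 and 171 CPM in treated 1 and 2, and 840 and 542 CPM in 3 and 4. For Klf2, Btg2, Klf4 and Junb the pairs of treated libraries overlapped. The chemokine Cxcl1 had 1.64 (SE 0.30, adjusted p = 0.26), Sfi1 1.21 and Wfdc17 1.08. All 82 ribosomal protein genes had a value above 0 (median 0.37, camera adjusted p = 7.9e-25, adjusted p = 0.62 with an estimated correlation), among them Rpl21 at 0.72, Rpl14 at 0.69 and Rpl5 at 0.58. The ribosomal protein list mean was higher in treated cultures 1 and 2 than in 3 and 4 by 0.40, and the median was 0.59 with the first pair alone and 0.17 with the second. Respiratory chain subunits rose as a list (74 members, median 0.15, camera adjusted p = 1.1e-04, adjusted p = 0.62 with an estimated correlation), with Ndufa4 at 0.48. That call ended once the coding length trend was removed (median 0.10, adjusted p = 0.12) and with treated cultures 3 and 4 alone (0.06, adjusted p = 0.50). Mural and smooth muscle markers rose as a list (10 members, median 0.21, camera adjusted p = 0.014, adjusted p = 0.62 with an estimated correlation) but not without treated library 4 (median 0.06, adjusted p = 0.068) or Swiss Webster naive library 1 (0.16, adjusted p = 0.053). The list call was also lost with treated cultures 1 and 2 alone (median 0.041, camera adjusted p = 0.103). Rgs5 had 1.03 and Notch3 0.58. Rgs5 stood at 45.9 and 48.98 CPM in treated libraries 1 and 2, below the Swiss Webster naive libraries (50.9 CPM). It stood at 221 and 243 CPM in treated libraries 3 and 4 and at 281 CPM in the C57BL/6 library. Notch3 stood at 26.02 CPM in treated library 4 against 10.6 to 13.1 CPM in the other treated ones.

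Pan-neuronal genes fell as a list (22 members, median -0.47, camera adjusted p = 1.2e-04, adjusted p = 0.62 with an estimated correlation), with Map2 at -0.94, the neuronal tubulin Tubb3 at -1.18 and Uchl1 at -0.83; with treated cultures 3 and 4 alone the median was -0.05 (adjusted p = 0.50). Schwann cell markers fell as a list (17 members, median -0.33, camera adjusted p = 0.014, adjusted p = 0.62 with an estimated correlation; adjusted over the list alone 7 fell and 2 rose), with Sox10 at -0.97 and Cnp at -0.76. This call was lost without Swiss Webster naive library 1 (median -0.25) or treated library 3 (-0.44, camera adjusted p = 0.13). It was also lost with treated cultures 1 and 2 alone (-0.56, adjusted p = 0.079) and with 3 and 4 alone (-0.36, adjusted p = 0.073). Cell proliferation genes were lower as a list (30 members, median -0.28, camera adjusted p = 0.0099, adjusted p = 0.62 with an estimated correlation), but not without treated library 3 (-0.18, adjusted p = 0.18) or 4 (-0.25, adjusted p = 0.070) or with pooled naive groups (-0.09, adjusted p = 0.77). Nusap1 had -0.68 and Mcm2 -0.50; in the naive C57BL/6 library Nusap1 stood at 28.2 CPM, below the treated mean of 59.9 ± 12.2 CPM. The lowest unadjusted p among falling values belonged to Clca3a2 (-1.51, adjusted p = 0.18), Prdm16 (-1.01), the myelin protein Pmp2 (-1.28), the opioid precursor Penk (-1.76) and Aatk (-1.09). The mRNA values of Il6ra (-0.51), Calca (-0.24), Scn10a (-0.21), Ntrk1 (-0.07) and Mpz (0.05) did not pass, and Arc was below the level tested. Without treated QuantSeq library 4, 12 lists were called in place of 7.

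Footprint and mRNA changes were then set side by side to ask whether translation per mRNA changed. Across 9368 genes measured in both assays, the treatment fold changes correlated with Pearson's r of 0.43 and Spearman's rho of 0.38, and 60.5% of genes had the same sign in both. These are values across genes, which are not independent replicates. Within the treated group, deviations of footprint and QuantSeq libraries of the same number correlated at 0.31, 0.21, 0.21 and 0.17 across genes, although footprint library 2 correlated best with QuantSeq library 1, and the naive pairs at only 0.07. Cultures shared by the assays may give like signs without a treatment effect, but whether the numbers mark shared cultures is not certain, and the share due to this was not computed. Of the 48 genes called in footprints and tested in QuantSeq, 46 had the same sign in QuantSeq. Leaving out single libraries gave r from 0.35 to 0.44.

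Wtap was the 1 gene called for a change in footprints apart from its mRNA, and with the naive cultures of both strains pooled 0 were called by limma, since naive C57BL/6 footprints of Wtap (69.0 ± 2.51 CPM) were as low as treated ones. The difference of the changes was -3.29 (SE 0.36, adjusted p = 0.0010), since Wtap mRNA had a QuantSeq log2 fold change of -0.16 (SE 0.21). By limma, 0 genes had a higher and 1 a lower ratio of footprints to mRNA among 9368; at an unadjusted p below 0.05 there were 455 higher and 111 lower. Dact3 (-2.17, adjusted p = 0.084), a regulator of Wnt signalling, and Mrpl14 (-1.86, adjusted p = 0.11), a mitochondrial ribosomal protein, came next on the lower side, followed by Vkorc1l1 (-1.43) and Sobp (-1.05). On the higher side, the small heat shock protein Hspb8 had 1.18 (adjusted p = 0.14), the splicing factor Prpf39 1.31, Ing1 1.02, Wdr45b 0.99 and the RNA helicase Ddx39b 1.31. Of 82 ribosomal protein genes, 44 had a value above 0 (median 0.03, camera adjusted p = 0.72), with Rps27a at 0.97 and Rpl36a at 0.88. The ribosomal protein ratio was lower as a list with treated cultures 1 and 2 alone (median -0.18, adjusted p = 1.3e-04), but not with 3 and 4 alone (0.22, adjusted p = 0.18).

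Macrophage markers (17 members, median -0.28, camera adjusted p = 0.0033), mitochondrially encoded proteins (9 members, median -0.28, camera adjusted p = 0.0033) and immediate early genes (28 members, median -0.11, camera adjusted p = 0.013) had lower ratios as lists. Each had adjusted p = 0.97 with an estimated correlation, and 0 members of the 3 lists passed in limma over all genes. Fos had -0.62 (SE 0.80), Egr1 -0.07, Junb -0.31, Calca 0.57, Scn10a -0.20, Ntrk1 -0.10, Il6ra 0.09 and Mpz 0.01, none past the threshold. Without treated footprint library 3 none of the 3 lists was called (macrophage median -0.08, adjusted p = 0.58; the other 2 lists, adjusted p = 0.053), and cell proliferation genes were the 1 list called, with a higher ratio (median 0.31, adjusted p = 0.033). The mitochondrial list was not called without Swiss Webster naive footprint library 2 (median -0.01, adjusted p = 0.26), with quantile normalisation or with pooled naive groups. The immediate early gene list was not called without Swiss Webster naive footprint library 1, naive QuantSeq library 2, treated footprint library 1 or 4 or treated QuantSeq library 3 (adjusted p = 0.068 to 0.23) or with quantile normalisation, and its median was 0.13 with pooled naive groups. Gene calls were 2 without Swiss Webster naive footprint library 1 or treated footprint library 3.

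The fourth comparison set naive C57BL/6 against naive Swiss Webster footprints, 2 libraries each, and so describes strain and supplier together. Footprints of 7 of 30 immediate early genes were lower in C57BL/6: Junb stood at 209 ± 0.721 CPM (SD, n = 2) against 423 ± 18.2 CPM in Swiss Webster, and Egr1 at 163 ± 15.9 against 489 ± 292 CPM. Footprints of Ifit3, at 63.3 ± 3.26 against 5.78 ± 2.52 CPM, and of the chemokine Cxcl10, at 41.3 ± 2.07 against 8.08 ± 0.104 CPM, were higher in C57BL/6. The myelin gene Mpz, at 188 ± 14.1 against 44.8 ± 3.20 CPM, and the surface protein Thy1, at 910 ± 10.9 against 224 ± 13.3 CPM, were higher in C57BL/6. Wtap was lower in C57BL/6, at 69.0 ± 2.51 against 822 ± 71.6 CPM.

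By limma, 112 of 11144 genes were higher and 137 lower in C57BL/6; at an unadjusted p below 0.05 there were 1253 higher and 927 lower, the opposite balance. The libraries did not overlap in 61.7% of genes, where chance gives 33.3%. Higher genes included Hist1h4m (log2 5.76, SE 0.51, adjusted p = 3.7e-04), Ifit3 (3.30), the complement protease C1s1 (3.18), Palmd (2.77), Ifit3b (2.75), Dpep1 (2.64), the growth factor Ptn (2.57), Pop4 (2.49), Mndal (2.27) and Cxcl10 (2.22). Lower genes included Hist1h2al (-5.47, SE 0.36, adjusted p = 8.4e-05), Ifi202b (-4.65), Eno1b (-4.27), Myrip (-3.98), Wtap (-3.55), Pianp (-3.40), Foxe1 (-3.19), Serpina3f (-2.98), Stc2 (-2.93) and Ocel1 (-2.53). Ifi202b and Serpina3f were listed at 0 in both C57BL/6 libraries, and Hist1h4m, C1s1, Dpep1 and Ifit3b in Swiss Webster and Hist1h2al, Eno1b, Myrip, Pianp and Foxe1 in C57BL/6 lay near or below the level of 3 reads. Fold changes of these genes depend on the 1 CPM added before the log. Several belong to families of near-identical genes, such as the histones, in which reads can be shared between copies. In QuantSeq, with 1 C57BL/6 library and no test, 131 of 214 genes called in footprints had the same sign (61.2%, against 54.9% of all 9368 genes), and Wtap and Junb had -0.15 and 0.00. Hist1h4m had 0 reads in all 7 QuantSeq libraries, so its mRNA was not measured.

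Of 30 immediate early genes, 7 were lower in C57BL/6 among all genes and 12 adjusted over the list alone (median -0.72, camera adjusted p = 1.8e-11, adjusted p = 0.25 with an estimated correlation). Junb (-1.01, adjusted p = 0.0041), Ier5 (-0.88), Egr2 (-1.22), Nr4a1 (-1.92) and Egr1 (-1.44, adjusted p = 0.040) were among the 7, and Fos (-1.32, adjusted p = 0.13) and Arc (0.54) did not pass. Feedback regulators of the ERK pathway were lower as a list (13 members, median -0.31, camera adjusted p = 0.0086, adjusted p = 0.25 with an estimated correlation), and the phosphatase Dusp1 was 1 of 2 members lower adjusted over the list alone (-1.13). All 31 cell proliferation genes had a value above 0 (median 0.47, camera adjusted p = 1.6e-07, adjusted p = 0.85 with an estimated correlation). Of these, 3 were higher among all genes and 12 adjusted over the list alone, with the mitotic genes Kif11 at 1.09, Cenpe at 1.30 and Ccnb1 at 0.90. In QuantSeq the mean of 30 of these genes lay lower in the C57BL/6 library than in Swiss Webster naive cultures, by a log2 difference of -0.47. Macrophage markers were higher as a list (20 members, median 0.47, camera adjusted p = 0.010, adjusted p = 0.97 with an estimated correlation), with Ctss at 0.84 and Pf4 at 2.28, though not without C57BL/6 library 2 (median 0.45, adjusted p = 0.10).

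Schwann cell markers went both ways, with Mpz higher (2.04, adjusted p = 0.0023) and Sox10 lower (-0.72, adjusted p = 0.036), and the list was not past the threshold (median 0.12, camera adjusted p = 0.53). Thy1 (2.02), the glial sodium pump subunit Atp1a2 (1.52) and the chemokine Cxcl12 (1.25) were higher, and the nociceptor sodium channel Scn11a was lower (-1.31, adjusted p = 0.036). The neuropeptide gene Gal had -2.55 (adjusted p = 0.051), at 69.3 ± 0.556 against 411 ± 6.35 CPM. Scn10a (-0.63), Calca (-0.49), Ntrk1 (-0.69) and Il6ra (-0.51) did not pass. Counts of genes were 25 and 35 without C57BL/6 library 1 or 2, 29 and 26 without Swiss Webster naive library 1 or 2, and 773 without treated library 3, which enters this fit through the spread. The lone library left in a group was then taken to vary like the other groups.

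The last comparison set footprints against QuantSeq mRNA over all 3 groups, as a relative ratio per gene. Vinculin (Vcl), a protein of cell adhesions, had 753 ± 102 CPM (SD, n = 8) in footprints and 5.21 ± 1.31 CPM (n = 7) in QuantSeq, and the collagen Col6a1 had 518 ± 65.7 and 14.1 ± 2.45 CPM. The ribosomal protein gene Rps12 stood low, at 127 ± 33.4 and 4011 ± 897 CPM. The lowest ratio belonged to Lrrc17, at 13.2 ± 8.82 and 24496 ± 11646 CPM.

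By limma, 4225 of 9368 genes had a higher and 3081 a lower footprint share than mRNA share. The excess of higher genes was absent with footprints taken per kilobase of coding sequence (3735 higher, 3807 lower) and at a mean of at least 20 CPM (2118 and 2114). In 52.9% of genes the libraries of the assays did not overlap, where chance gives 0.031%. The higher genes were Vcl (6.87, SE 0.13, adjusted p = 3.1e-15), the actin-binding Pfn1 (5.92), the glycolytic enzyme Eno1 (5.78), Sept9 (5.45), Col6a1 (5.10), Prrc2a (5.03), Slc9a8 (4.91), the clathrin adaptor Ap2a1 (4.77), Ncstn (4.68) and Col12a1 (4.67). The lower genes were Lrrc17 (-10.87, SE 0.34, adjusted p = 2.6e-13), Vps8 (-7.67), Cnot3 (-6.54), Metrn (-5.98), Mpv17l (-5.81), Chchd2 (-5.37), Timm22 (-5.16), Zfas1 (-5.10), Rps12 (-5.06) and D3Ertd254e (-4.96). Zfas1 hosts small nucleolar RNAs and has no coding length in the annotation. In every QuantSeq library Pfn1 stood at 25.4 CPM or less and Eno1 at 11.7 CPM or less. Lrrc17 took 2.61% and 2.92% of reads in the Swiss Webster naive QuantSeq libraries. The rule for counting reads is not stated, and 4913 genes share a locus entry with another gene. Whether reads were assigned to the wrong gene was not tested, so these extreme ratios are not evidence of translation per mRNA. On mm10, Vcl lies on chromosome 14 from 20929398 to 21033676 and Lrrc17 on chromosome 5 from 21543559 to 21575904.

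Of 82 ribosomal protein genes, 67 were lower and 9 higher (median -1.88, camera adjusted p = 3.2e-14, adjusted p = 0.73 with an estimated correlation), with Rpl36a at -4.41, Rps27a at -4.08, Rps3a1 at -3.85 and Rps14 at -3.52. Of 26 fibroblast markers, 25 were higher and 1 lower (median 2.36, camera adjusted p = 4.2e-06, adjusted p = 0.071 with an estimated correlation), with Fbn1 at 3.66, Col6a2 at 3.66 and Col5a2 at 2.56. The macrophage genes Cd68 (3.96) and C1qb (3.61) were higher, although their list was not past the threshold (median 0.95, camera adjusted p = 0.19). Junb (0.92), Scn10a (1.89), Ntrk1 (1.80) and Mpz (0.76) were higher and Egr1 was lower (-1.30), while Fos (-0.13), Calca (0.09) and Il6ra (0.26) did not pass. Footprints come from the whole coding sequence and QuantSeq reads from 1 end, and the ratio rose with coding length (Spearman's rho 0.28 across genes). With footprints taken per kilobase of coding sequence, the call of the ribosomal protein list ended (median -0.77, adjusted p = 0.19) and Scn10a turned to -0.32.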

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

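The tests of coding length, translation per mRNA, untreated variation, the share of neurons, depth, the naive level and Wtap mRNA were chosen after the result was seen.

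By Dixon's ratio, 8 of 147 groups of 4 treated libraries held 1 library far from the other 3; chance gives about 5%. In treated footprint library 4, Dact3 stood at 35.5 CPM against 57.1 to 57.8 in the others, and Scn10a at 85.7 CPM against 44.3 to 48.6. In treated footprint library 3, Junb stood at 599.5 CPM against 497 to 512. In treated QuantSeq library 4, Cnp stood at 28.9 CPM against 19.2 to 20.8 and Notch3 at 26.02 CPM against 10.6 to 13.1. As list means of log2 footprints minus the Swiss Webster naive mean, endothelial markers stood at -0.42 in treated library 4 against 0.14 to 0.18, integrated stress response genes at 0.39 in treated library 3 against 0.14 to 0.15, and macrophage markers at -0.87 in treated library 3 against -0.06 to 0.01.

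Ribosomal protein genes were higher in treated cultures in both assays, which may reflect the treatment, a bias with transcript length, or variation between cultures. Removing a trend on coding length, fitted on the other genes, took the footprint median from 0.48 to 0.25 (SE of the mean 0.12; camera adjusted p = 2.9e-08, adjusted p = 0.69 with an estimated correlation). Coding length is thus argued against as the whole cause of the footprint rise by little more than that error, and it could account for much of it. In QuantSeq the median went from 0.37 to 0.31 (SE of the mean 0.19), a smaller part. A change in translation per mRNA cannot be told apart from none: the median difference between the assays was 0.035, with an SE of the mean of 0.19. Untreated variation stays open, since the naive C57BL/6 QuantSeq library lay 0.59 above the Swiss Webster naive mean, within the range of the treated libraries, although strain may have moved it. Within the treatment, the QuantSeq list mean was 0.40 higher in cultures 1 and 2 than in 3 and 4, about as large as the rise itself, while footprints differed by -0.00243 between the pairs.

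Treated cultures 1 and 2 had lower neuronal genes than treated cultures 3 and 4. These are the numbers of the libraries, and whether the 2 assays read the same cultures is not stated. Depth is argued against, as the depths of the pairs overlapped in 2 of 2 assays. A lower share of neurons in cultures 1 and 2 is a candidate explanation: the 4 neuronal lists differed by a median of -0.79 in footprints and -0.84 in QuantSeq, while 6 lists of other cell types differed by medians of -0.02 and -0.16. Those 6 ranged from -0.34 to 0.47 in footprints and from -0.39 to 0.22 in QuantSeq, within their pooled error (variance ratios 2.04 and 1.61, with a limit of 3.11). That error is wide in footprints, where macrophage and endothelial markers differed by 0.81 and 0.55 between cultures 3 and 4. Mural (-0.34 and -0.39), satellite glia (-0.16 and -0.32) and Schwann cell markers (-0.08 and -0.16) were lower in cultures 1 and 2 in both assays. Endothelial markers were higher in both (0.31 and 0.22), and fibroblast and macrophage markers differed in sign between the assays. The gap may thus not be confined to neurons. The labels give no difference between these cultures that could serve as a biological explanation, and a change within neurons stays open.

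The footprint calls of the treatment comparison rest on the 2 Swiss Webster naive libraries. Of the 56 called genes, 23 had a C57BL/6 naive mean nearer to the treated than to the Swiss Webster naive mean, between the bounds set for a level shared by both naive groups and for a level particular to Swiss Webster naive libraries, so these cannot be told apart for the called genes; 13 of the 56 were also called for strain, and in 50 the treated mean lay beyond both naive means. For Wtap, a change in mRNA is argued against by the QuantSeq log2 fold change of -0.16 (SE 0.21). High Wtap footprints in these 2 libraries may come from a treatment effect on translation, or from these naive cultures or their libraries, since the naive C57BL/6 footprints were as low as the treated ones. An allele carried by some animals of the outbred Swiss Webster stock was not tested.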

How the results depend on the processing

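Of the alternatives below, the percentile scaling, voom weights, pairs of treated cultures and coding length were chosen after the data were seen, as was leaving out libraries for the lists and correlations. Where no cause is named, the cause was not tested.

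For footprints by treatment (56 genes), counts within 1.5 times were given by an added value of 0.1 or 5, a mean of at least 1 or 20 CPM, quantile normalisation, robust variances, voom and the length trend. The count was 30 with no filter, which tests more genes, 88 with TMM factors, 26 with pooled naive groups, 27 with Swiss Webster libraries only, 1359 with the replicate number as a block, which keeps only treated cultures 1 and 2 in the contrast, 86 with percentile scaling, 1232 with treated cultures 1 and 2 only (448 higher, 784 lower) and 1862 with 3 and 4 only (1259 higher, 603 lower), so the balance of 14 higher and 42 lower depended on the pair of cultures. Leaving out single libraries gave 1 (without Swiss Webster naive library 2) to 155 (without treated library 3).

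For QuantSeq by treatment (1 gene), the count was 0 with an added value of 5, a mean of at least 20 CPM, no filter or pooled naive groups, and 2 with quantile normalisation, TMM factors, percentile scaling or the length trend removed. It was 1940 with the number block, 2062 with treated cultures 1 and 2 only and 52 with 3 and 4 only, and 0 to 2 leaving out single libraries. For the ratio by treatment (1 gene), it was 2 with an added value of 5, quantile normalisation, TMM factors or the length trend removed, 0 with pooled naive groups, 181 and 91 with treated cultures 1 and 2 or 3 and 4 only, and 1 to 2 leaving out single libraries. For strain (249 genes), it was 2540 with the number block (1495 higher, 1045 lower), 164 with voom, and 25 (without C57BL/6 library 1) to 773 (without treated library 3). For footprints against QuantSeq (7306 genes), it was 4232 with a mean of at least 20 CPM, where fewer genes were tested, and 7030 to 7367 leaving out single libraries.

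With an estimated correlation, 0 lists held in each comparison. With fry, 3 lists were called for footprints by treatment, 2 of them among the 10 that camera called (ribosomal proteins and Schwann cell markers), 0 of 7 for QuantSeq, 0 of 3 for the ratio and 19 against 2 for footprints against QuantSeq. With treated cultures 1 and 2 only, 16 lists were called for footprints and 11 for QuantSeq; quantile normalisation gave 1 for the ratio, and coding length correction 4 for footprints against QuantSeq. Leaving out single libraries gave 6 to 13, 5 to 12, 1 to 4, 3 to 6 and 2 to 2 lists in the order of the comparisons.

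The correlation of treatment fold changes was 0.381 (Pearson) and 0.348 (Spearman) with treated cultures 3 and 4 only, and 0.347 to 0.439 and 0.312 to 0.393 leaving out single libraries. Called lists whose median or camera direction turned were, in footprints, macrophage markers with treated cultures 1 and 2 only (-0.075), and neuropeptides (0.16) and pan-neuronal genes (0.20) with 3 and 4 only, and neuropeptides without treated footprint library 1 (0.017); in QuantSeq, cell proliferation with 1 and 2 only (-0.0838); and in the ratio, immediate early genes with pooled naive groups (0.13) or cultures 1 and 2 only (0.0078), macrophage markers with 1 and 2 only (0.064) and mitochondrially encoded proteins with 3 and 4 only (0.036). Scn10a turned to -0.32 in footprints against QuantSeq with the coding length correction. Of the 26 called genes named for footprints by treatment, 436 alternative values kept the call, 182 lost it and 0 turned direction; Wtap stayed called in all but pooled naive groups.

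Depth limits genes under 0.906 to 2.01 CPM in footprints, where 3 reads are reached.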

Other observations

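The tests of the 2 pairs of treated cultures and the overlap of treatment with strain were chosen after the result was seen; the test of other splits was fixed before.

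Footprints were compared with each pair of treated cultures taken alone. Of 28 immediate early genes, 8 were higher with cultures 1 and 2 and with cultures 3 and 4: Btg2, Zfp36, Egr1, Ier2, Nr4a1, Klf4, Fos and Fosb. Of 82 ribosomal protein genes, 30 were higher with both pairs, and of 17 Schwann cell markers 7 were lower with both, namely L1cam, Ngfr, Sox10, Erbb3, Plp1, Gfra1 and Cryab. Over 11005 genes, 205 were higher with both pairs, 198 lower with both and 32 opposite, against 50.0, 43.0 and 112 from the product of the counts. Both pairs were set against the same 2 naive libraries, which by themselves give like signs. With no effect, simulated fold changes had a covariance of 0.042 and a correlation of 0.51, against 0.092 and 0.47 in the data. On average 0 simulated genes were called higher in both and 0.05 lower in both. The simulated libraries varied independently, without the gap between the pairs seen in the data. These simulated counts therefore cannot show how many shared calls would arise without a treatment effect.

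Immediate early genes stood lowest in naive C57BL/6 footprints and highest in treated Swiss Webster footprints, while their QuantSeq list mean in the C57BL/6 library lay at the Swiss Webster naive level (0.01). Between the treatment and strain comparisons, which share the Swiss Webster naive libraries, 4 genes were higher and 9 lower in both, Wtap among the latter. The fold changes had a correlation of 0.50 (simulated 0.57) and a covariance of 0.0997 (simulated 0.042). Simulated data without effects gave 0 of each, but held no gene particular to the shared naive libraries. Such a gene would be called in both comparisons, so the simulated 0 does not bear on that case.

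For footprints against QuantSeq, 1 of 100 splits of the 15 libraries, the real one, gave as many genes. It called 7478 in a fit with 1 assay term, and 5972 was the highest of the others. The 2 assays read different parts of the mRNA, so this outcome could be foreseen and does not bear on the meaning of the ratio. The other comparisons hold groups of 2 libraries, so splits were not counted.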
